A study of Medicago truncatula with 48 samples.

How the data were processed

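Seedlings of Medicago truncatula A17 were grown from surface-sterilised seeds that germinated for 2 days in the dark at 22 °C and were then moved to plates with or without oospores of Pythium oligandrum, under 16 h of light and 8 h of dark, per the labels' protocols. Each of the 48 samples was RNA of 5 pooled whole seedlings, in 8 groups of 6 biological replicates (2 treatments at days 3, 5, 7 and 14). Stranded mRNA libraries were sequenced as paired reads of 150 bases, per the labels' protocols. FastQC, HTSeq and edgeR 3.24.3 are named in the submitters' processing notes, which give no role for them, and the annotation was release 5.0 of A17, per the file headers. The aligner, the filter on low genes and the strand setting of the counting were not given in the sources used here.

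The deposited values are a signal per gene and library, normalised read counts, and from their steps they are read counts that the authors divided by 1 factor per library. The table held 22279 genes, and sums over genes ran from 46.1 to 53.9 M per library. They differed between treatments at day 5 (47.7 to 49.6 M in controls and 50.8 to 52.2 M in treated libraries) and at day 7 (46.6 to 48.5 M and 50.1 to 53.9 M). In a search over each whole column, 100% of the values in all 48 libraries were whole multiples of 1 step within a tolerance of 0.001, which implied 35.1 to 73.1 M reads per library. A stricter rule on values up to 20 steps, which needed 95% of them to be whole, recovered reads in 13 libraries and not in the other 35, where low values were few. Count tests were therefore run only on the 10 day 3 libraries recovered by that rule (5 control and 5 treated), as an alternative. The lowest gene mean was 46.2 and the median gene mean 854 normalised counts, so counting error was small beside the spread between pools for most genes. Genes with near-identical copies, such as the chalcone synthases, are uncertain because the counting could split their reads.

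Gene descriptions were taken from the deposited table. No description stood for 268 genes, 2704 were listed as hypothetical proteins and 914 as putative proteins, and 9 genes were listed by symbol only. Of the gene identifiers, 0 matched the reference table of 39590 genes, so no coordinates were used here.

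Libraries of each group were first compared in all 120 pairs, and chi-square per gene on implied reads was 8.17 to 215 where counting noise alone gives 1, so that no pair was treated as 1 library. The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(value + 1), with all 48 libraries in a model of 8 groups and 40 residual degrees of freedom. Genes were kept with a value of at least 10 in at least 6 libraries, which removed 0 genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, for each day, the average over 4 days, the treatment by day interaction (an F test) and control day 14 against control day 3. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

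A set of 27 gene lists was built from words in the descriptions and tested by camera with a preset correlation of 0.01, adjusted over 108 tests of lists and days, with an estimated correlation, fry and an exact permutation test of the list mean (6 against 6 libraries, smallest possible p of 0.00216) as alternatives. The named genes were, for each day, the 6 that rose and the 6 that fell most among called genes with a mean of at least 10 over that day, the same direction in the medians and an informative description, with the 2 members of smallest p in each called list. For the average effect they were 8 up and 8 down, and for the interaction the 10 of smallest p. The tests, lists, named gene rule and most alternatives were fixed before the data were examined, and the alternatives without control day 14 replicate 3, with a mean of at least 200, with a photosynthesis covariate, with limma on 10 libraries and with permutation of list means were added after the data were seen. Other alternatives were pseudocounts of 0.1 and 5, other filters, rescaling by size factors, quantile normalisation, the replicate number as a block, only the libraries of a comparison, a constant prior variance, weights per library, a log2 fold change of at least 1, count tests (edgeR 4.0.16 and DESeq2 1.42.0) and leaving out each replicate number.

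The fits were tested on simulated data in which 50 genes each were changed by 0.5, 1, 2 or 3 log2 units. For day 3 the shares recovered were 74, 90, 100 and 100%, for day 5 70, 92, 100 and 100%, for day 7 60, 88, 100 and 100%, and for day 14 54, 88, 100 and 98%. False calls made up 4.21, 7.18, 5.95 and 3.95% of the calls at the 4 days, and camera, tested on simulated lists at day 3 alone, called the changed list and 0 of 40 unchanged lists. Simulated genes were drawn independently of each other. The run therefore could not test the preset correlation on lists whose genes vary together. Each simulated gene also had 1 setting of spread for all 8 groups and no change between days in controls. The shares recovered and falsely called thus do not cover groups that differ in spread or a library that stands apart. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 read the tables, and Matplotlib 3.10.9 drew the figures.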

Results

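RNA was sequenced from seedlings of Medicago truncatula A17, a reference line of this model legume, kept on plates with or without oospores of Pythium oligandrum, a soil oomycete that parasitises other microbes and is used in plant protection. Pools of 5 seedlings were collected after 3, 5, 7 and 14 days, with 6 biological replicates per treatment and day, which gave 48 libraries. Normalised read counts of 22279 genes summed to 46.1 to 53.9 M per library (median 50.2 M), and the smallest step between values in each library implied 35.1 to 73.1 M reads (median 48.6 M). Gene descriptions come from the deposited table, and genome coordinates were not analysed here. Unless stated otherwise, changes are treated minus control differences on the log2(normalised count + 1) scale with their SE, levels are mean ± SD, n is 6 pools per group, and p-values are two-sided limma values adjusted by Benjamini-Hochberg over all genes.

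**Figure D1:**
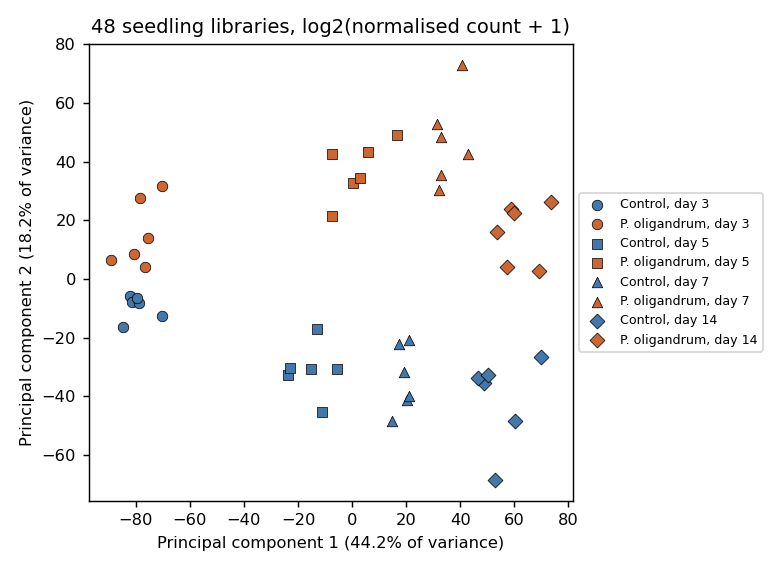
Principal component scores of the 48 libraries from log2(normalised count + 1), component 1 on the x axis (44.2% of the variance) and component 2 on the y axis (18.2%), in arbitrary units, 1 point per library, with colour for treatment and shape for day. Along component 2 the treated libraries lay between 2.82 and 73.0 and the control libraries between -68.6 and -5.76.

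After 3 days, which gives the earliest response measured, genes of flavonoid synthesis were among those that rose most and lipid transfer proteins among those that fell most. A geraniol 8-hydroxylase (MtrunA17_Chr1g0197891), a cytochrome P450, rose by 4.05 ± 0.81 (adjusted p = 4.34e-04), from 52.4 ± 38.8 to 1677 ± 1752 normalised counts, and exceeded the highest control in 4 of 6 treated pools. A trans-cinnamate 4-monooxygenase (MtrunA17_Chr1g0210091), an enzyme at the entry to phenylpropanoid synthesis, rose by 3.36 ± 0.67 (adjusted p = 3.61e-04), from 19.9 ± 17.3 to 365 ± 506 normalised counts, with 5 of 6 pools above the highest control. A pair of chalcone synthases, the first committed step of flavonoid synthesis, rose by 3.26 ± 0.82 (adjusted p = 0.00424) in MtrunA17_Chr1g0201421 and by 2.96 ± 0.59 (adjusted p = 4.14e-04) in MtrunA17_Chr1g0201381. Their treated pools stood at 295 ± 374 and 561 ± 656 normalised counts, against 11.9 ± 10.9 and 32.9 ± 16.3 in controls, with 4 and 5 of 6 pools above the highest control. A CAP superfamily protein (MtrunA17_Chr2g0295371), of the family that holds the first class of pathogenesis-related proteins, rose by 2.83 ± 0.42 (adjusted p = 4.76e-06) and exceeded the highest control in 6 of 6 pools. The call for MtrunA17_Chr1g0201421 was lost without replicate 1 or 3 in every group (adjusted p = 0.0707 and 0.0527) and in a fit of the day 3 libraries alone (0.0741). It was also lost on the 10 libraries with recovered reads by edgeR (0.0630) and by limma (0.224), with an adjusted p of 0.00105 to 0.224 over its 22 alternatives. The call for MtrunA17_Chr1g0201381 was lost by limma on those 10 libraries (adjusted p = 0.0705, with 8.86e-05 to 0.0705 over its 22 alternatives). A germin (MtrunA17_Chr6g0449761), a cell wall protein of the cupin superfamily, rose by 3.00 ± 0.53 (adjusted p = 7.55e-05) from only 3.32 ± 3.47 normalised counts and exceeded the highest control in 3 of 6 pools, with adjusted p = 0.0682 by edgeR, 0.105 by limma on those 10 libraries and 1.78e-05 to 0.105 over its 22 alternatives.

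Among the genes that fell most were 4 annotated as lipid transfer proteins, small secreted proteins that bind lipids, while of the 42 genes so described 2 rose and 7 fell. MtrunA17_Chr1g0205201 fell by 3.73 ± 0.32 (adjusted p = 7.23e-11), from 1559 ± 443 to 121 ± 50.5 normalised counts. MtrunA17_Chr1g0205171 fell by 3.01 ± 0.36, MtrunA17_Chr4g0003641 fell by 2.82 ± 0.27 and MtrunA17_Chr1g0185321 fell by 2.62 ± 0.30, and all 4 lay below the lowest control in 6 of 6 treated pools. A PGG domain-containing protein (MtrunA17_Chr8g0343361) fell by 2.23 ± 0.29 (adjusted p = 5.27e-07). A shikimate O-hydroxycinnamoyltransferase (MtrunA17_Chr3g0132831) fell by 2.26 ± 0.68 (adjusted p = 0.0179) and lay below the lowest control in 4 of 6 pools. Its call was lost when replicate 1, 4 or 5 was left out of every group (adjusted p = 0.0768, 0.0876 and 0.121). It was also lost with a pseudocount of 0.1 (0.0523), with quantile normalisation (0.0757) and on the 10 libraries with recovered reads by edgeR (0.111), DESeq2 (0.0730) and limma (0.0800), with an adjusted p of 1.60e-04 to 0.121 over its 21 alternatives.

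Of 108 genes of flavonoid and isoflavonoid biosynthesis, 28 rose and 6 fell (37 and 9 adjusted over the list alone). The list median was 0.26 (camera adjusted p = 7.98e-04, and adjusted p = 0.852 with an estimated correlation). The list mean was 10.2, 9.47, 9.74, 10.2, 9.09 and 9.29 log2 units in treated replicates 1 to 6, against 8.90 to 9.35 in controls, so that replicates 5 and 6 lay within the control range. Control replicate 3 alone set its lower end. The other 5 controls lay at 9.23 to 9.35, above treated replicate 5. An isoflavone 7-O-glucosyltransferase (MtrunA17_Chr6g0462571) rose by 1.41 ± 0.23, whereas the chalcone synthase MtrunA17_Chr7g0252331 fell by 1.36 ± 0.20 from 15228 ± 2052 normalised counts. In the list of 236 NLR immune receptors, 26 rose and 6 fell (25 and 6 adjusted over the list alone). Over the list, the median log2 change was 0.08 (camera adjusted p = 0.0354, and adjusted p = 0.852 with an estimated correlation). Its TIR domain members MtrunA17_Chr2g0302011 and MtrunA17_Chr8g0353351 rose by 1.02 ± 0.15 and 0.27 ± 0.05. Among 75 photosynthesis genes, 0 rose and 13 fell (0 and 15 adjusted over the list alone). In this list the median change was -0.19 (camera adjusted p = 4.83e-05, and adjusted p = 0.852 with an estimated correlation). A chlorophyll A-B binding protein (MtrunA17_Chr3g0124681) fell by 1.05 ± 0.15 and a ribulose-bisphosphate carboxylase lysine N-methyltransferase (MtrunA17_Chr2g0296791) fell by 0.71 ± 0.09. Of 367 ribosomal protein genes, a list that includes plastid ribosomal proteins, 28 rose and 29 fell (28 and 29 adjusted over the list alone). The median of the list stood at 0.11 (camera adjusted p = 0.00319, and adjusted p = 0.897 with an estimated correlation). The ribosomal proteins S9 (MtrunA17_Chr1g0154431) and L7/L12 (MtrunA17_Chr6g0450121) had the smallest p in that list and changed by -0.57 ± 0.08 and -0.62 ± 0.10, against the direction of its median and test.

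Of 12 nitrate transport and assimilation genes, 0 rose and 3 fell (0 and 6 adjusted over the list alone). Their median change was -0.26 (camera adjusted p = 8.00e-04, and adjusted p = 0.445 with an estimated correlation). It was 0.26, 0.37 and 0.38 at days 5, 7 and 14, with no camera call. An ABC-type nitrate transporter (MtrunA17_Chr5g0399071) fell by 0.95 ± 0.15, and MtrunA17_Chr1g0189971, which fell by 1.58 ± 0.22, is annotated as an ammonium transporter. Among 27 aquaporins, the water channels of the major intrinsic protein family, 1 rose and 6 fell (2 and 6 adjusted over the list alone). Their median log2 fold change was -0.18 (camera adjusted p = 0.0131, and adjusted p = 0.852 with an estimated correlation). MtrunA17_Chr4g0030861 fell by 1.68 ± 0.29 and MtrunA17_Chr2g0333771 fell by 1.58 ± 0.18. Of 27 iron and zinc homeostasis genes, 2 rose and 8 fell (3 and 9 adjusted over the list alone). The list median was -0.12 (camera adjusted p = 0.0308, and adjusted p = 0.445 with an estimated correlation). Ferric-chelate reductases, which reduce iron for uptake, changed by -1.10 ± 0.16 (MtrunA17_Chr2g0291481) and -0.77 ± 0.13 (MtrunA17_Chr4g0058571). In the phosphate list of 55 genes, many of them sugar phosphate transporters, 0 rose and 10 fell (0 and 11 adjusted over the list alone). Over the list, the median log2 change was -0.10 (camera adjusted p = 0.0252, and adjusted p = 0.852 with an estimated correlation). A phosphate transporter (MtrunA17_Chr8g0367931) fell by 0.79 ± 0.12 and an SPX domain-containing protein (MtrunA17_Chr1g0166651), of a family that senses phosphate status, fell by 0.59 ± 0.12. Of 30 terpenoid and saponin genes, 1 rose and 6 fell (2 and 7 adjusted over the list alone). In this list the median change was -0.06 (camera adjusted p = 0.0402, and adjusted p = 0.852 with an estimated correlation). Squalene monooxygenase (MtrunA17_Chr4g0049291) fell by 0.86 ± 0.13 and beta-amyrin 24-hydroxylase (MtrunA17_Chr7g0235551), a step of triterpene saponin synthesis, fell by 1.06 ± 0.18.

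In all, 3648 genes were called at day 3, of which 1653 rose and 1995 fell, with 168 and 129 of them changed by at least 1 log2 unit. The count fell to 2319, 2363 and 2324 when replicate 1, 5 or 6 was left out of every group, and edgeR on reads recovered from 10 of the 12 libraries called 987 higher and 1948 lower. Quantile normalisation moved the aquaporin median to -0.12. Leaving out 1 replicate number at a time ended the list calls for NLR immune receptors (adjusted p = 0.115, 0.0699 and 0.0813 without replicate 1, 2 or 4), ribosomal proteins (adjusted p = 0.593, 0.0775 and 0.116 without replicate 3, 4 or 5), terpenoid genes (adjusted p = 0.0564, 0.0844 and 0.0560 without replicate 2, 5 or 6) and the phosphate list (adjusted p = 0.0580 without replicate 6), and an exact permutation test of the list mean gave adjusted p = 0.139 for flavonoid genes.

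After 5 days a leucine-rich repeat gene, a pair of germins and enzymes of flavonoid synthesis were among the genes that rose most. A leucine-rich repeat-containing gene (MtrunA17_Chr7g0222871) rose 176-fold, by 7.46 ± 0.71 (adjusted p = 6.33e-11), from 167 ± 98.05 to 26623 ± 11572 normalised counts. The germins MtrunA17_Chr2g0285871 and MtrunA17_Chr6g0449761 rose 131-fold and 62.7-fold, by 7.03 ± 0.38 (adjusted p = 1.52e-17) and 5.97 ± 0.53 (adjusted p = 1.35e-11). A licodione synthase (MtrunA17_Chr7g0224561), a cytochrome P450 of flavonoid metabolism, rose 66.2-fold, by 6.05 ± 0.56 (adjusted p = 4.02e-11). The chalcone synthase MtrunA17_Chr5g0395591 rose 75.8-fold, by 6.24 ± 0.90 (adjusted p = 7.12e-07), and the geraniol 8-hydroxylase MtrunA17_Chr1g0197891 rose 114-fold. Each of these 6 genes exceeded the highest control in 6 of 6 treated pools.

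On the other side, a gene with a TMEM189 B domain (MtrunA17_Chr3g0098711) fell by 4.11 ± 0.51 (adjusted p = 2.37e-08), from 482 ± 208 to 29.1 ± 18.8 normalised counts. A premnaspirodiene oxygenase (MtrunA17_Chr5g0446161), a P450 acting on sesquiterpenes, fell by 2.59 ± 0.50 (adjusted p = 9.76e-05). A trans-zeatin O-beta-D-glucosyltransferase (MtrunA17_Chr7g0265041), which conjugates the cytokinin zeatin, fell by 2.29 ± 0.44 (adjusted p = 8.34e-05). A GATA-type transcription activator (MtrunA17_Chr3g0128821) fell by 2.29 ± 0.23 (adjusted p = 3.63e-10), and the UDP-glycosyltransferase MtrunA17_Chr1g0207861 fell by 2.19 ± 0.29 (adjusted p = 1.49e-07). The lipid transfer protein MtrunA17_Chr1g0205201 again fell by 2.41 ± 0.32 (adjusted p = 1.57e-07), with 5 of 6 pools below the lowest control, where the other 5 of these genes had 6 of 6.

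Of 108 flavonoid and isoflavonoid genes, 54 rose and 13 fell (57 and 14 adjusted over the list alone). The median of the list stood at 0.40 (camera adjusted p = 1.89e-11, and adjusted p = 0.445 with an estimated correlation). A 2'-hydroxyisoflavone reductase (MtrunA17_Chr5g0404481) and an isoflavone 2'-hydroxylase (MtrunA17_Chr4g0052861), enzymes on the route to pterocarpan phytoalexins, rose by 2.83 ± 0.23 and 1.76 ± 0.15. Among 133 pathogenesis-related proteins, chitinases and glucanases, 39 rose and 17 fell (39 and 18 adjusted over the list alone). Across these genes the median change was 0.05 (camera adjusted p = 0.00196, and adjusted p = 0.852 with an estimated correlation). A Bet v I/major latex protein (MtrunA17_Chr2g0295064), of the family of intracellular pathogenesis-related proteins, rose 35.3-fold to 108454 ± 39966 normalised counts, and a chitin-binding Barwin domain protein (MtrunA17_Chr7g0274181) rose by 2.15 ± 0.18. Of 681 receptor-like kinases, 222 rose and 64 fell (232 and 73 adjusted over the list alone). Their median log2 fold change was 0.09 (camera adjusted p = 1.28e-04, and adjusted p = 0.749 with an estimated correlation). MtrunA17_Chr4g0048791 and MtrunA17_Chr2g0318841 of the DLSV family rose by 3.43 ± 0.31 and 1.64 ± 0.15. In the list of 69 WRKY transcription factors, which regulate plant defence genes, 20 rose and 6 fell (23 and 6 adjusted over the list alone). The list median was 0.14 (camera adjusted p = 4.90e-04, and adjusted p = 0.749 with an estimated correlation). MtrunA17_Chr4g0004911 rose by 3.82 ± 0.37 and MtrunA17_Chr7g0224801 by 2.98 ± 0.27.

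Among NLR immune receptors, 58 rose and 19 fell (59 and 20 adjusted over the list alone). Over the list, the median log2 change was 0.07 (camera adjusted p = 0.0160, and adjusted p = 0.852 with an estimated correlation), with rises of 2.59 ± 0.26 in MtrunA17_Chr8g0343631 and 2.60 ± 0.27 in MtrunA17_Chr8g0362611. Of 95 genes for peroxidases and the oxidative burst, 26 rose and 6 fell (27 and 9 adjusted over the list alone). In this list the median change was 0.04 (camera adjusted p = 0.0401, and adjusted p = 0.852 with an estimated correlation), and after quantile normalisation the median became -0.02, with 27 up and 11 down. The peroxidases MtrunA17_Chr4g0013171 and MtrunA17_Chr4g0013181 rose by 3.48 ± 0.33 and 2.69 ± 0.22. Among photosynthesis genes, 0 rose and 39 fell (0 and 45 adjusted over the list alone). The median of the list stood at -0.36 (camera adjusted p = 2.14e-10, and adjusted p = 0.852 with an estimated correlation). The chlorophyll A-B binding proteins MtrunA17_Chr1g0204671 and MtrunA17_Chr8g0382991 changed by -1.66 ± 0.23 and -1.33 ± 0.18. In the ribosomal protein list, 124 rose and 26 fell (154 and 35 adjusted over the list alone). Across these genes the median change was 0.17 (camera adjusted p = 2.03e-05, and adjusted p = 0.852 with an estimated correlation), whereas after quantile normalisation 50 rose and 36 fell. MtrunA17_Chr1g0180521 (S5 domain 2-type) and MtrunA17_Chr5g0432551 (S9) rose by 0.51 ± 0.09 and 0.31 ± 0.06.

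At day 5, 6212 genes were called, 3090 up and 3122 down, while changes of at least 1 log2 unit were 680 up and 180 down. Quantile normalisation gave 2490 up and 3923 down and moved the medians of the pathogenesis-related, WRKY and NLR lists to 0.0035, 0.09 and 0.05, and limma with weights per library called 9467. The call for peroxidases was lost when 1 replicate number was left out (adjusted p = 0.0750, 0.0703 and 0.0508 without replicate 1, 2 or 4).

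The most genes of the 4 days were called after 7 days. The leucine-rich repeat-containing gene MtrunA17_Chr7g0222871 rose 221-fold, by 7.79 ± 0.71 (adjusted p = 7.07e-12). A Barwin domain protein (MtrunA17_Chr1g0190651), of a domain shared with a class of pathogenesis-related proteins, rose 146-fold, by 7.19 ± 0.58 (adjusted p = 3.70e-13), from 46.99 ± 42.8 to 5735 ± 2651 normalised counts. The germin MtrunA17_Chr2g0285871 rose 94.8-fold (adjusted p = 2.02e-16), a methyltransferase (MtrunA17_Chr7g0218261) 81.5-fold (adjusted p = 6.98e-10) and the chalcone synthase MtrunA17_Chr5g0395591 78.4-fold (adjusted p = 2.62e-07). The Bet v I/major latex protein MtrunA17_Chr2g0295064 rose 63.03-fold, by 5.98 ± 0.41 (adjusted p = 1.14e-14), and reached 87572 ± 33466 normalised counts against 1410.3 ± 544 in controls. All 6 exceeded the highest control in 6 of 6 treated pools.

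A galactose oxidase (MtrunA17_Chr1g0155971) fell by 3.18 ± 0.52 (adjusted p = 2.78e-06) and the TMEM189 B domain gene MtrunA17_Chr3g0098711 fell by 3.14 ± 0.51 (adjusted p = 2.36e-06). The UDP-glycosyltransferase MtrunA17_Chr1g0207861 fell by 2.94 ± 0.29 (adjusted p = 7.70e-11), and the cytochrome P450 MtrunA17_Chr1g0207841, whose identifier lies close to it, fell by 2.76 ± 0.37 (adjusted p = 5.33e-08). The trans-zeatin glucosyltransferase MtrunA17_Chr7g0265041 and the premnaspirodiene oxygenase MtrunA17_Chr5g0446161 changed by -2.64 ± 0.44 and -2.59 ± 0.50. Each of these 6 lay below the lowest control in 6 of 6 treated pools.

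Of 236 NLR immune receptors, 119 rose and 16 fell (123 and 16 adjusted over the list alone). Their median log2 fold change was 0.30 (camera adjusted p = 1.41e-08, and adjusted p = 0.677 with an estimated correlation). The TIR domain genes MtrunA17_Chr8g0362611 and MtrunA17_Chr6g0454821 rose by 3.73 ± 0.27 and 0.87 ± 0.07. Among 69 WRKY factors, 38 rose and 5 fell (38 and 6 adjusted over the list alone). The list median was 0.38 (camera adjusted p = 7.95e-07, and adjusted p = 0.482 with an estimated correlation), including MtrunA17_Chr7g0224801 at 3.14 ± 0.27 and MtrunA17_Chr7g0228941 at 1.70 ± 0.15. Among receptor-like kinases, 304 rose and 128 fell (316 and 144 adjusted over the list alone). Over the list, the median log2 change was 0.18 (camera adjusted p = 2.03e-05, and adjusted p = 0.677 with an estimated correlation), and MtrunA17_Chr8g0361261 and MtrunA17_Chr2g0318841 rose by 2.88 ± 0.22 and 2.15 ± 0.15. For flavonoid and isoflavonoid genes, 56 rose and 16 fell (56 and 16 adjusted over the list alone). In this list the median change was 0.53 (camera adjusted p = 3.48e-07, and adjusted p = 0.677 with an estimated correlation). A flavonoid 3'-monooxygenase (MtrunA17_Chr3g0086651) rose 58.6-fold and the isoflavone 2'-hydroxylase MtrunA17_Chr4g0052861 by 1.86 ± 0.15. In the pathogenesis-related list, 48 rose and 22 fell (48 and 22 adjusted over the list alone). The median of the list stood at 0.02 (camera adjusted p = 0.0117, and adjusted p = 0.852 with an estimated correlation), and the median became -0.01 after quantile normalisation. A further Bet v I/major latex protein (MtrunA17_Chr6g0462291) rose by 5.19 ± 0.38.

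Of 75 photosynthesis genes, 2 rose and 23 fell (2 and 23 adjusted over the list alone). Across these genes the median change was -0.17 (camera adjusted p = 0.00283, and adjusted p = 0.897 with an estimated correlation). A chlorophyll A-B binding protein (MtrunA17_Chr1g0204521) and a photosystem II protein (MtrunA17_Chr1g0183221) changed by -1.91 ± 0.22 and -1.47 ± 0.17. In the heat shock list of 104 genes, 13 rose and 40 fell (13 and 41 adjusted over the list alone). Their median log2 fold change was -0.21 (camera adjusted p = 0.0160, and adjusted p = 0.852 with an estimated correlation). A chaperonin-binding protein (MtrunA17_Chr5g0398901) fell by 0.52 ± 0.07, and MtrunA17_Chr5g0436781, which rose by 2.35 ± 0.25, is annotated as a nematode resistance protein-like gene rather than a chaperone. Among ribosomal protein genes, 10 rose and 55 fell (4 and 18 adjusted over the list alone). The list median was -0.09 (camera adjusted p = 0.00939, and adjusted p = 0.897 with an estimated correlation), and after quantile normalisation 4 rose and 162 fell. The L30e protein MtrunA17_Chr6g0481341 rose by 1.37 ± 0.17 and the L2 protein MtrunA17_Chr7g0244891 fell by 0.56 ± 0.08. In the phosphate list, 6 rose and 21 fell (7 and 22 adjusted over the list alone). Over the list, the median log2 change was -0.15 (camera adjusted p = 0.0403, and adjusted p = 0.852 with an estimated correlation), with the sugar phosphate transporters MtrunA17_Chr2g0291851 at -0.997 ± 0.14 and MtrunA17_Chr1g0149401 at 0.47 ± 0.06.

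At day 7, 9588 genes were called, 5043 up and 4545 down, with 1136 and 349 changed by at least 1 log2 unit, whereas quantile normalisation gave 3941 up and 6394 down and moved the medians of the photosynthesis and ribosomal lists to -0.28 and -0.20. The calls for the phosphate list (adjusted p = 0.0524 and 0.101 without replicate 4 or 6) and for ribosomal proteins (adjusted p = 0.0627 without replicate 6) were lost when 1 replicate number was left out of every group.

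**Figure D2:**
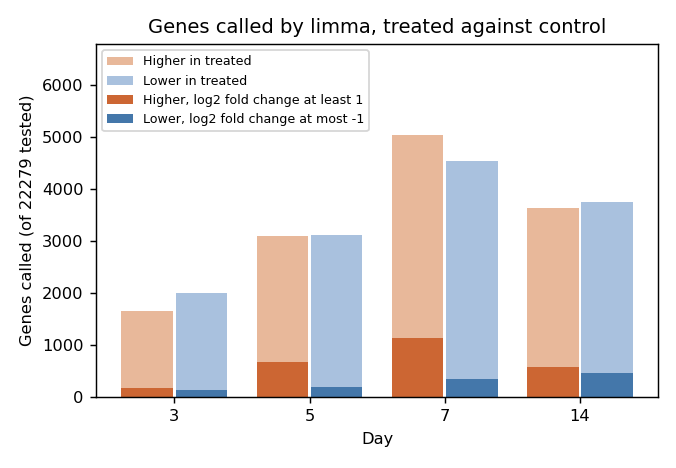
Genes called at each day by limma (adjusted p under 0.05 over 22279 genes), with the day on the x axis and the number of genes on the y axis. Light bars show all genes higher or lower in treated seedlings and dark bars those changed by at least 1 log2 unit. The number called went from 3648 at day 3 to 9588 at day 7 and was 7392 at day 14.

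**Figure D3:**
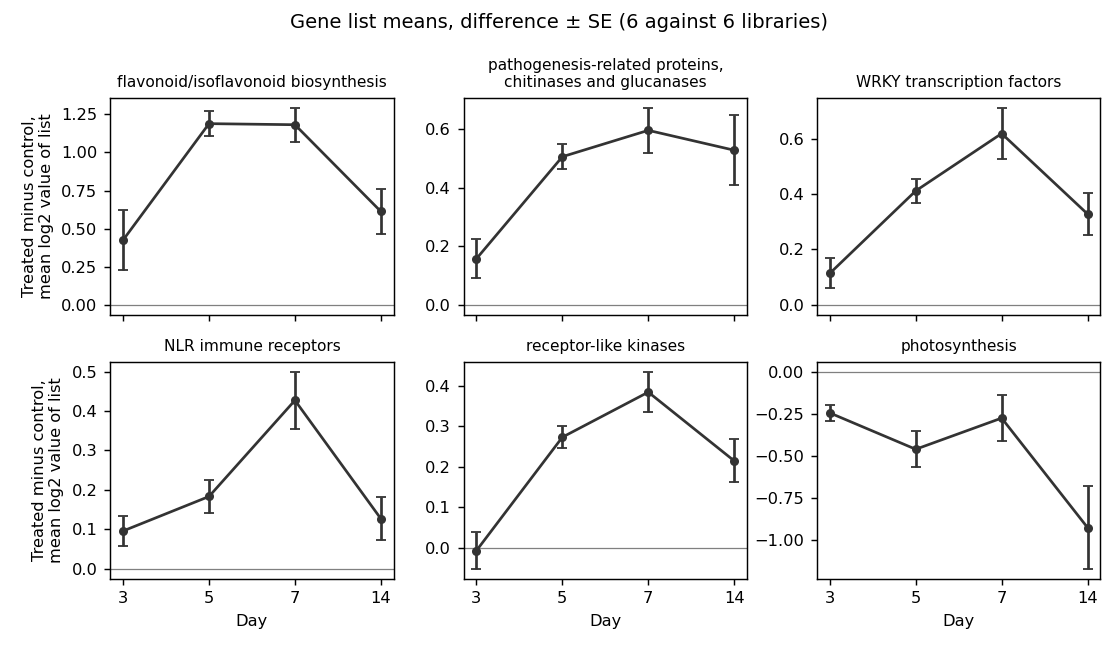
Difference of the mean log2 value of 6 gene lists between treated and control libraries (y axis, log2 units) at each day (x axis), with bars of 1 SE from 6 against 6 libraries. The photosynthesis list lay below 0 on all 4 days and was lowest at day 14, at -0.93 ± 0.25.

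After 14 days, 3 Bet v I/major latex proteins were among the genes that rose most, while of the 28 genes so described 10 rose and 9 fell (10 and 10 after quantile normalisation), with a median change of 0.14. In the same comparison the photosynthesis list had its lowest median change of the 4 days. The leucine-rich repeat-containing gene MtrunA17_Chr7g0222871 rose 44.9-fold, by 5.49 ± 0.71 (adjusted p = 1.29e-07). The Bet v I/major latex proteins MtrunA17_Chr6g0462311, MtrunA17_Chr2g0295064 and MtrunA17_Chr2g0295091 rose 33.5-fold, 27.2-fold and 22.9-fold (adjusted p = 2.63e-11, 4.73e-11 and 6.52e-10). A thaumatin family gene (MtrunA17_Chr1g0180121) rose by 4.63 ± 0.62 (adjusted p = 2.29e-07) and the Barwin domain protein MtrunA17_Chr1g0190651 by 4.69 ± 0.58 (adjusted p = 5.73e-08). Each of these exceeded the highest control in 6 of 6 treated pools.

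A BURP domain-containing protein (MtrunA17_Chr1g0147271) fell by 4.59 ± 0.88 (adjusted p = 6.97e-05), and lay below the lowest control in 3 of 6 treated pools. A carbonic anhydrase (MtrunA17_Chr6g0450641), which interconverts carbon dioxide and bicarbonate, fell by 4.38 ± 0.67 (adjusted p = 2.51e-06), with controls at 13278 ± 22662 and treated pools at 408 ± 379 normalised counts. A glycine rich protein (MtrunA17_Chr5g0438501) fell by 3.82 ± 0.85 and a WSD1 O-acyltransferase (MtrunA17_Chr4g0040261), of a family that makes wax esters, fell by 3.20 ± 0.65, and these calls were lost in a fit of the day 14 libraries alone (adjusted p = 0.0936 and 0.0530, with 3.01e-04 to 0.0936 and 5.74e-05 to 0.0530 over all alternatives). Both lay below the lowest control in 3 of 6 pools. The galactose oxidase MtrunA17_Chr1g0155971 fell by 3.54 ± 0.52 (adjusted p = 1.16e-06) and a transferase (MtrunA17_Chr8g0378151) fell by 3.26 ± 0.59 (adjusted p = 3.27e-05), with 6 and 4 of 6 pools below the lowest control.

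Of 75 photosynthesis genes, 1 rose and 68 fell (2 and 68 adjusted over the list alone). In this list the median change was -0.89 (camera adjusted p = 2.72e-28, and adjusted p = 0.677 with an estimated correlation). A photosystem II PsbX protein (MtrunA17_Chr1g0150841) fell by 2.09 ± 0.23 and a ribulose-bisphosphate carboxylase (MtrunA17_Chr7g0215381), the carbon-fixing enzyme, fell by 2.14 ± 0.23. Control replicate 3 stood at a list mean of 13.5 log2 units against 12.1 to 12.6 in the other 5 controls, and without it 61 members fell and 1 rose, with a median of -0.66. In the heat shock list, 8 rose and 33 fell (9 and 33 adjusted over the list alone). The median of the list stood at -0.10 (camera adjusted p = 0.0202, and adjusted p = 0.852 with an estimated correlation), and the DnaJ proteins MtrunA17_Chr4g0014501 and MtrunA17_Chr4g0063651 changed by -1.64 ± 0.24 and -0.67 ± 0.10. For both DnaJ genes control replicate 3 also stood above the other 5 controls (9.48 against 7.48 to 8.19, and 12.7 against 11.9 to 12.2 log2 units). Among ribosomal protein genes, 8 rose and 61 fell (8 and 53 adjusted over the list alone). Across these genes the median change was -0.04 (camera adjusted p = 0.0110, and adjusted p = 0.897 with an estimated correlation), with S6 (MtrunA17_Chr2g0294021) and L31 (MtrunA17_Chr1g0155441) at -0.66 ± 0.09 and -0.70 ± 0.10.

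Of 133 pathogenesis-related proteins, chitinases and glucanases, 45 rose and 16 fell (49 and 17 adjusted over the list alone). Their median log2 fold change was 0.29 (camera adjusted p = 1.02e-04, and adjusted p = 0.749 with an estimated correlation). Of 108 flavonoid and isoflavonoid genes, 43 rose and 12 fell (47 and 13 adjusted over the list alone). The list median was 0.34 (camera adjusted p = 9.50e-04, and adjusted p = 0.852 with an estimated correlation). The isoflavone 2'-hydroxylase MtrunA17_Chr4g0052851 rose 16.2-fold, whereas an isoflavone-7-O-beta-glucoside malonyltransferase (MtrunA17_Chr7g0219101), which modifies stored isoflavone glucosides, fell by 0.80 ± 0.11. Of 83 phenylpropanoid and lignin genes, 30 rose and 8 fell (33 and 8 adjusted over the list alone). Over the list, the median log2 change was 0.34 (camera adjusted p = 0.00196, and adjusted p = 0.852 with an estimated correlation). Caffeoyl-CoA O-methyltransferase (MtrunA17_Chr4g0053021) and caffeate O-methyltransferase (MtrunA17_Chr5g0448091), enzymes of monolignol synthesis, rose by 2.95 ± 0.33 and 1.25 ± 0.14. In the WRKY list, 25 rose and 5 fell (25 and 5 adjusted over the list alone). In this list the median change was 0.20 (camera adjusted p = 0.00101, and adjusted p = 0.799 with an estimated correlation), with MtrunA17_Chr8g0348311 up by 0.89 ± 0.13 and MtrunA17_Chr1g0147881 by 0.67 ± 0.08. Among receptor-like kinases, 211 rose and 55 fell (217 and 59 adjusted over the list alone). The median of the list stood at 0.15 (camera adjusted p = 1.74e-04, and adjusted p = 0.749 with an estimated correlation), with MtrunA17_Chr8g0360851 up by 2.22 ± 0.24 and MtrunA17_Chr7g0247831 by 0.50 ± 0.05. For NLR immune receptors, 55 rose and 23 fell (55 and 23 adjusted over the list alone). Across these genes the median change was 0.11 (camera adjusted p = 0.0498, and adjusted p = 0.852 with an estimated correlation), and MtrunA17_Chr8g0362611 and MtrunA17_Chr2g0302011 rose by 2.37 ± 0.27 and 1.24 ± 0.15.

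At day 14, 7392 genes were called, 3636 up and 3756 down, with 571 and 449 changed by at least 1 log2 unit. A fit of the 12 day 14 libraries alone called 4033, and without control replicate 3 the count was 6089 (3131 up and 2958 down). The NLR call was lost without that library (adjusted p = 0.0911) or without 1 replicate number in every group (adjusted p = 0.255 and 0.0535 without replicate 4 or 6), as was the ribosomal call (adjusted p = 0.0508 and 0.210 without replicate 4 or 5). With the photosynthesis list mean as a covariate the calls for the carbonic anhydrase, the DnaJ proteins MtrunA17_Chr4g0014501 and MtrunA17_Chr4g0063651, S6 and L31 ended (adjusted p = 0.136, 0.116, 0.235, 0.102 and 0.0704), and quantile normalisation moved the ribosomal median to -0.08.

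**Figure D4:**
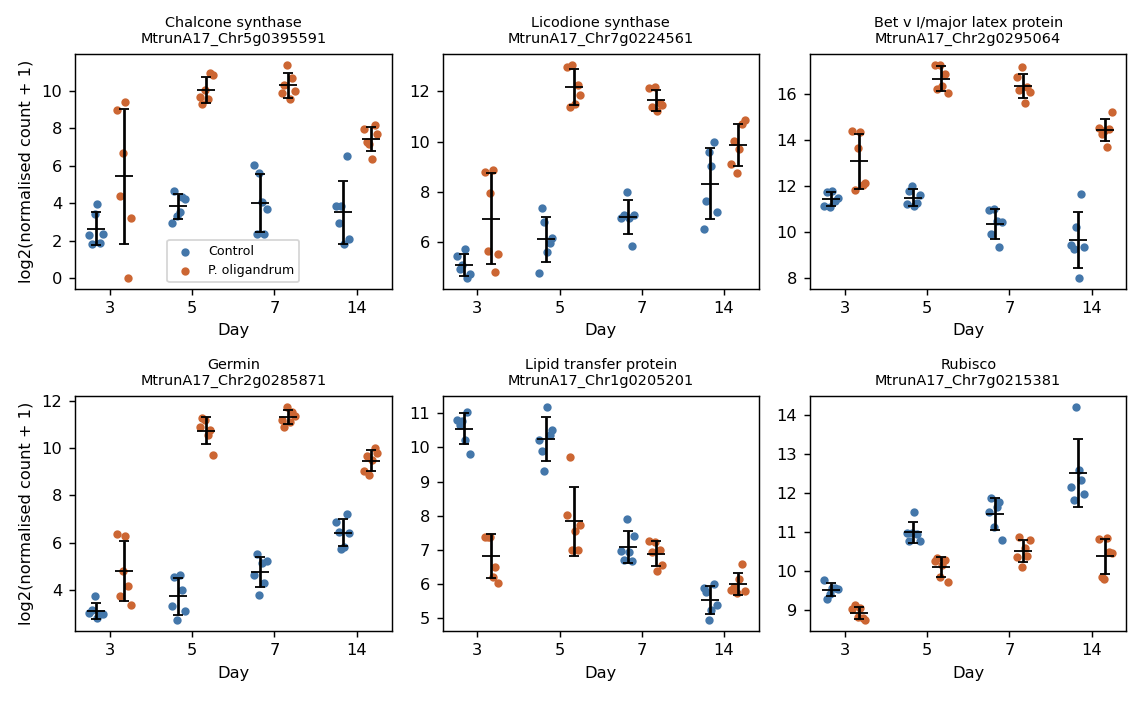
Levels of 6 genes as log2(normalised count + 1) on the y axis against day on the x axis, 1 point per library, with the mean and SD of 6 libraries per group as black bars. Treated libraries of the chalcone synthase, licodione synthase, Bet v I and germin genes lay above the controls at days 5 and 7, and the lipid transfer protein lay below them at day 3.

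**Figure D5:**
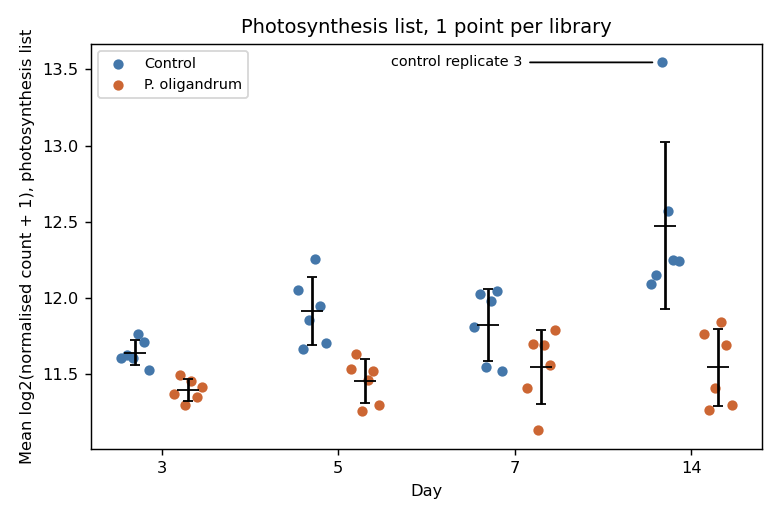
Mean log2(normalised count + 1) over the 75 photosynthesis genes on the y axis against day on the x axis, 1 point per library, with the mean and SD of 6 libraries per group as black bars. Control replicate 3 of day 14 stood at 13.5, above the other 5 controls of that day at 12.1 to 12.6.

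The effect averaged over the 4 days asked which genes differed between treated and control seedlings regardless of time. The leucine-rich repeat-containing gene MtrunA17_Chr7g0222871 rose by 5.84 ± 0.35 (adjusted p = 1.75e-17), the geraniol 8-hydroxylase MtrunA17_Chr1g0197891 by 4.94 ± 0.41, the chalcone synthase MtrunA17_Chr5g0395591 by 4.82 ± 0.45 and the Barwin domain protein MtrunA17_Chr1g0190651 by 4.77 ± 0.29. The germin MtrunA17_Chr2g0285871 rose by 4.59 ± 0.19, the methyltransferase MtrunA17_Chr7g0218261 by 4.54 ± 0.35, the Bet v I protein MtrunA17_Chr2g0295064 by 4.38 ± 0.20 and an FAD-binding domain protein (MtrunA17_Chr1g0197161) by 4.19 ± 0.20. The TMEM189 B domain gene MtrunA17_Chr3g0098711 fell by 2.61 ± 0.25, the galactose oxidase MtrunA17_Chr1g0155971 fell by 2.27 ± 0.26 and the premnaspirodiene oxygenase MtrunA17_Chr5g0446161 fell by 1.93 ± 0.25. The WSD1 O-acyltransferase MtrunA17_Chr4g0040261 fell by 1.84 ± 0.33. The carbonic anhydrase MtrunA17_Chr6g0450641 fell by 2.03 ± 0.34, a call that was lost with the photosynthesis list mean as a covariate (adjusted p = 0.257, with 4.23e-07 to 0.257 over its 19 alternatives). Falls were also called for a WEB family protein (MtrunA17_Chr8g0369191), which fell by 1.99 ± 0.18, a small auxin-up RNA (MtrunA17_Chr4g0036711), which fell by 1.86 ± 0.17, and the GATA-type activator MtrunA17_Chr3g0128821, which fell by 1.81 ± 0.12 (adjusted p = 1.38e-16).

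On average over days 11803 genes were called, 5951 up and 5852 down (4831 and 6897 after quantile normalisation), with 532 and 153 changed by at least 1 log2 unit. Of all 22279 genes, 14605 were called on at least 1 day and 302 rose on all 4 days, where independent calls would give 8.47. Among those 302 were the leucine-rich repeat-containing gene MtrunA17_Chr7g0222871, the germin MtrunA17_Chr2g0285871, the licodione synthase MtrunA17_Chr7g0224561 and the CAP superfamily protein MtrunA17_Chr2g0295371. The genes that fell on all 4 days numbered 583, where independent calls would give 9.61, and 592 rose on 1 day and fell on another. Days 5 and 7 shared 2223 rising genes (699 if independent) and 1900 falling genes (637 if independent), and their fold changes correlated across genes at 0.835, while those of days 3 and 14 correlated at 0.401. Genes are not independent replicates in these correlations, and each day had its own control libraries.

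The treatment by day interaction asked whether the effect of P. oligandrum changed with time. The germin MtrunA17_Chr2g0285871 differed from control by 1.69, 7.03, 6.57 and 3.06 log2 units at days 3, 5, 7 and 14 (SE 0.38, limma interaction adjusted p = 1.99e-09), and a further germin (MtrunA17_Chr6g0449731) by 1.58, 4.82, 4.20 and 1.20 (SE 0.30, limma interaction adjusted p = 1.03e-08). Several genes rose at day 3 and fell later. They were a protein annotated with kinase and WD40-like domains (MtrunA17_Chr2g0317491), which differed by 0.46, -0.74, -0.70 and -0.42, and its relative MtrunA17_Chr8g0347471, which differed by 0.88, -1.64, -1.67 and -0.59. An RNA polymerase sigma factor (MtrunA17_Chr3g0126401), of a family that directs plastid transcription, differed by 0.53, -1.43, -1.23 and -0.65, and a Ninja family protein (MtrunA17_Chr7g0219081), of a family that acts in hormone signalling, by 0.63, -0.69, -0.41 and -0.46. Daily calls on both sides held for each of these 4 genes. A zinc/iron permease (MtrunA17_Chr2g0328931), a metal transporter, had its call at days 7 and 14, with differences of -0.12, 0.00, 0.32 and 0.91 over the 4 days. A NAM family transcription factor (MtrunA17_Chr5g0442771) differed by -0.15, 2.25, 2.29 and 1.28, an oxoglutarate/iron-dependent dioxygenase (MtrunA17_Chr1g0184101) by -0.16, 1.38, 1.94 and 1.39 and a TauE transmembrane protein (MtrunA17_Chr7g0265481) by -0.29, 0.73, 1.21 and -0.14, with no call at day 3 in these 3 genes.

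The limma F test called 7218 of 22279 genes for the interaction, and 76 of the 96 other genes named for the daily or average effects were among them. Weights per library raised that count to 10914, and leaving out replicate 5 of every group lowered it to 4367.

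Control seedlings at day 14 against control seedlings at day 3 gave the size of the change without treatment over the same period. Development was not separated there from time on the plates or the day of collection. A chalcone synthase (MtrunA17_Chr3g0125351) rose from 0.390 ± 0.615 to 4624 ± 3134 normalised counts, by 11.51 ± 0.89 log2 units, and ferric-chelate reductases rose by 11.37 ± 0.89 (MtrunA17_Chr8g0348521) and 9.52 ± 0.84 (MtrunA17_Chr8g0348531). A gene annotated as stress up-regulated Nod 19 (MtrunA17_Chr2g0292581) was listed at 0 in all 6 control libraries of day 3 and stood at 5716 ± 3813 at day 14. A cation efflux protein (MtrunA17_Chr3g0119281) rose by 9.14 ± 0.72 and a BURP domain-containing protein (MtrunA17_Chr3g0139431) by 8.72 ± 0.61. A peroxidase (MtrunA17_Chr6g0467251) fell by 8.44 ± 0.57, from 5910.1 ± 1298 to 37.3 ± 39.2 normalised counts, a transferase (MtrunA17_Chr3g0113181) fell by 6.95 ± 0.63 and an albumin I chain a gene (MtrunA17_Chr7g0225821), encoding a seed protein, fell by 6.49 ± 0.80. A patatin-like phospholipase (MtrunA17_Chr8g0335621) fell by 6.26 ± 0.58, a lipid transfer protein (MtrunA17_Chr4g0012961) fell by 6.15 ± 0.79 and a PB1 domain protein (MtrunA17_Chr4g0058471) fell by 6.15 ± 0.67. These genes were chosen by size after their values were seen, with the same limits on level and description as for treatment.

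Over time in controls, of 75 photosynthesis genes 57 rose and 3 fell (57 and 3 adjusted over the list alone), at a median of 0.70 (camera adjusted p = 4.96e-07, and adjusted p = 0.564 with an estimated correlation). Without control day 14 replicate 3, whose photosynthesis list mean stood apart, 53 of them rose and 7 fell, at a median of 0.51 (camera adjusted p = 7.11e-06, and adjusted p = 0.599 with an estimated correlation). Of 236 NLR immune receptors, 139 rose and 30 fell (140 and 31 adjusted over the list alone), at a median of 0.48 (camera adjusted p = 3.09e-06, and adjusted p = 0.322 with an estimated correlation). Of 367 ribosomal protein genes, 238 rose and 16 fell (238 and 16 adjusted over the list alone), at a median of 0.29 (camera adjusted p = 1.05e-07, and adjusted p = 0.496 with an estimated correlation). Among aquaporins 2 rose and 22 fell (3 and 22 adjusted over the list alone), at a median of -0.91 (camera adjusted p = 3.06e-06, and adjusted p = 0.269 with an estimated correlation), and among protease inhibitors 3 rose and 22 fell (3 and 22 adjusted over the list alone), at a median of -1.001 (camera adjusted p = 2.25e-04, and adjusted p = 0.269 with an estimated correlation). In the pathogenesis-related list, 20 rose and 72 fell (20 and 72 adjusted over the list alone), at a median of -0.52 (camera adjusted p = 1.99e-04, and adjusted p = 0.346 with an estimated correlation). For cell wall loosening proteins and extensins, 32 rose and 94 fell (32 and 95 adjusted over the list alone), at a median of -0.47 (camera adjusted p = 1.99e-04, and adjusted p = 0.496 with an estimated correlation). In all, 15155 genes were called, 8003 up and 7152 down, with 1744 and 2014 changed by at least 1 log2 unit, and camera called 14 of 27 lists, or 0 with an estimated correlation, where 3 had an unadjusted p below the threshold and the smallest adjusted p was 0.269. Without that library camera called 15 lists, which included the same 14 and the iron and zinc list (adjusted p = 0.0362), and 0 with an estimated correlation.

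Other lists had no camera call on any day with the preset correlation and all libraries. Of 34 protease inhibitors, 7, 6, 11 and 9 rose and 1, 4, 4 and 3 fell at the 4 days in turn (7, 6, 11 and 9 and 2, 5, 4 and 3 adjusted over the list alone, smallest camera adjusted p = 0.0503), whereas after quantile normalisation 6 rose and 7 fell at day 5. Of 40 jasmonate genes, 3, 9, 14 and 6 rose and 7, 4, 12 and 9 fell at the 4 days in turn (3, 9, 14 and 6 and 7, 5, 12 and 9 adjusted over the list alone, smallest camera adjusted p = 0.402), whereas after quantile normalisation 3 rose and 4 fell at day 3. Of 93 ethylene and ERF genes, 8, 23, 33 and 13 rose and 8, 12, 17 and 15 fell at the 4 days in turn (8, 23, 34 and 13 and 8, 12, 17 and 15 adjusted over the list alone, smallest camera adjusted p = 0.101). Of 70 glutathione S-transferases, 10, 12, 16 and 14 rose and 10, 13, 25 and 20 fell at the 4 days in turn (11, 12, 17 and 16 and 10, 15, 28 and 20 adjusted over the list alone, smallest camera adjusted p = 0.217), whereas after quantile normalisation 6 rose and 10 fell at day 3, 9 rose and 20 fell at day 5 and 12 rose and 34 fell at day 7. Of 13 nodule and symbiosis genes, 0, 2, 2 and 2 rose and 1, 1, 2 and 2 fell at the 4 days in turn (0, 2, 1 and 2 and 1, 1, 2 and 2 adjusted over the list alone, smallest camera adjusted p = 0.548), whereas after quantile normalisation 2 rose and 2 fell at day 5. Of 38 root endodermis and root hair genes, most of them Casparian strip proteins, 5, 3, 6 and 3 rose and 1, 9, 11 and 7 fell at the 4 days in turn (7, 3, 6 and 3 and 1, 10, 11 and 7 adjusted over the list alone, smallest camera adjusted p = 0.164), whereas after quantile normalisation 5 rose and 2 fell at day 3. Of 173 cell wall genes, 9, 20, 27 and 27 rose and 17, 11, 46 and 15 fell at the 4 days in turn (9, 19, 27 and 24 and 17, 10, 45 and 12 adjusted over the list alone, smallest camera adjusted p = 0.120). Of 93 genes in the cell cycle and histone list, which holds many histone methyltransferases, 3, 6, 14 and 13 rose and 3, 13, 17 and 9 fell at the 4 days in turn (0, 6, 12 and 12 and 1, 13, 14 and 8 adjusted over the list alone, smallest camera adjusted p = 0.271), whereas after quantile normalisation 4 rose and 17 fell at day 5 and 8 rose and 32 fell at day 7. Of 93 seed storage and late embryogenesis genes, 3, 7, 16 and 13 rose and 9, 17, 23 and 13 fell at the 4 days in turn (3, 7, 15 and 11 and 9, 16, 23 and 13 adjusted over the list alone, smallest camera adjusted p = 0.320). Of 47 auxin response genes, 3, 7, 13 and 8 rose and 2, 8, 7 and 9 fell at the 4 days in turn (2, 7, 13 and 8 and 2, 10, 7 and 10 adjusted over the list alone, smallest camera adjusted p = 0.368), whereas after quantile normalisation 5 rose and 11 fell at day 5 and 11 rose and 13 fell at day 7. Of 7 hypoxia genes, 0, 1, 1 and 3 rose and 1, 1, 2 and 0 fell at the 4 days in turn (0, 1, 1 and 3 and 1, 1, 2 and 0 adjusted over the list alone, smallest camera adjusted p = 0.101), and of 11 drought and abscisic acid genes, 3, 2, 4 and 4 rose and 1, 3, 1 and 1 fell at the 4 days in turn (3, 2, 4 and 5 and 1, 3, 1 and 1 adjusted over the list alone, smallest camera adjusted p = 0.381).

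Over the 27 lists and 4 days, camera with a preset correlation of 0.01 called 35 of 108 tests, 21 of them up and 14 down. With an estimated correlation it called 0, with a smallest adjusted p of 0.445, while 7 had an unadjusted p below the threshold. The rotation test fry made 37 calls, of which 26 were among those 35 in the same direction. It made no call for photosynthesis at days 3 and 7 (adjusted p = 0.194 and 0.187), NLR immune receptors at days 3 and 14 (adjusted p = 0.185 and 0.0832), the phosphate list at day 3 (adjusted p = 0.0624) and ribosomal proteins at days 3, 5, 7 and 14 (adjusted p = 0.339, 0.0709, 0.226 and 0.242). An exact permutation test of the list mean made 39 calls, of which 24 were among the 35. Besides flavonoid genes at day 3, it made no call for terpenoid genes at day 3 (adjusted p = 0.141), photosynthesis, heat shock and phosphate lists at day 7 (adjusted p = 0.139, 0.0835 and 0.194) or phenylpropanoid genes at day 14 (adjusted p = 0.128). Neither did it for NLR immune receptors at days 3 and 14 (adjusted p = 0.0903 and 0.107) or ribosomal proteins at days 3, 5 and 14 (adjusted p = 0.506, 0.157 and 0.157). With 1 replicate number left out, camera with the preset correlation also called rises at day 3 for protease inhibitors (adjusted p = 0.0335 and 0.0107 without replicate 2 or 5) and the pathogenesis-related list (adjusted p = 0.0264 and 0.0356 without replicate 5 or 6), and at day 5 a rise for phenylpropanoid genes (adjusted p = 0.0493 without replicate 5) and a fall for aquaporins (adjusted p = 0.0431 without replicate 3). At day 14 it then called rises for peroxidases (adjusted p = 0.0283 and 0.0471 without replicate 4 or 5), cell wall genes (adjusted p = 0.0170 and 0.0279 without replicate 4 or 5) and hypoxia genes (adjusted p = 0.0143 without replicate 4). It also called rises for protease inhibitors at day 3 without control day 14 replicate 3 (adjusted p = 0.0491) and for ethylene and ERF genes at day 7 after quantile normalisation (adjusted p = 0.0171). Of list tests with no camera call, fry called 11 and the permutation test 15. By fry, rises were called for protease inhibitors at days 3, 7 and 14 (adjusted p = 0.0408, 0.00767 and 0.0440), ethylene and ERF genes at days 5 and 7 (adjusted p = 0.00453 and 1.71e-05) and peroxidases at days 7 and 14 (adjusted p = 0.0142 and 0.0142). It also called rises for nitrate genes at days 5 and 7 (adjusted p = 0.0416 and 0.0462) and hypoxia genes at day 14 (adjusted p = 0.0195), and a fall for root genes at day 5 (adjusted p = 0.0416). By exact permutation, rises were called for protease inhibitors at days 3, 7 and 14 (adjusted p = 0.0161, 0.0161 and 0.0226), ethylene and ERF genes at days 3, 5 and 7 (adjusted p = 0.0334, 0.0292 and 0.0111) and peroxidases at days 3 and 7 (adjusted p = 0.0161 and 0.0111). Further rises were called for phenylpropanoid genes at days 5 and 7 (adjusted p = 0.0161 and 0.0480), nitrate genes at day 5 (adjusted p = 0.0431) and iron and zinc genes at day 14 (adjusted p = 0.0111), and falls for aquaporins at days 5 and 7 (adjusted p = 0.0334 and 0.0161) and the cell cycle list at day 7 (adjusted p = 0.0334). The median, the mean and the direction of the camera test differed in sign in 25 of the 108, of which camera with the preset correlation called 0. Rises called by fry or by permutation went with a median below 0 for peroxidases at day 7 (-0.0054). The same held for phenylpropanoid genes at days 5 and 7 (medians -0.01 and -0.08).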

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

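The tests of other splits of the libraries and the bound on the log2 change of conserved genes were set before their results were seen, and all other tests of explanations here were chosen after the pattern was seen. Of 316 groups of 6 libraries tested for a value far from the others, 15 had one, where chance gives 15.8, and 6 of the 15 were in control day 14 replicate 3.

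Control replicate 3 of day 14 stood far above the other 5 libraries on the log2 scale for PsbX MtrunA17_Chr1g0150841 (12.95, others 10.9 to 11.6), ribulose-bisphosphate carboxylase MtrunA17_Chr7g0215381 (14.2, others 11.8 to 12.6), the DnaJ proteins MtrunA17_Chr4g0014501 (9.48, others 7.48 to 8.19) and MtrunA17_Chr4g0063651 (12.7, others 11.9 to 12.2), and the photosynthesis list mean (13.5, others 12.1 to 12.6). Its sum of normalised counts was 50.9 M, against 46.1 to 46.8 M in the others, and in that library 2769 genes lay over 1 log2 unit from the mean of the other 5, against 62 to 809 in the other 47 libraries, while its nitrate list mean was 11.9 against 12.4 to 12.9. It had 42.6 M reads, below the 48.9 M of the next lowest control of that day, yet the 9 libraries with fewer reads had at most 319 such genes, which argues against depth as the cause. Its values correlated at 0.953 across genes with the other 5 and at most at 0.926 with another group, which argues against the label of another group. A larger share of green tissue stays open, because its root list mean lay only 0.0668 above the lowest of the other 5, whose SD was 0.194, and apart from that share no biological explanation was tested, as the design gives none within a group.

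The photosynthesis genes were lower in treated seedlings at day 14, with a list mean difference of -0.929 ± 0.247 (SE). Without control replicate 3 the difference was -0.715 ± 0.132, so that library alone does not account for it. A lower share of green tissue in the treated pools may account for it and stays open at day 14, where the root list mean differed by -0.0802 ± 0.117 without that library, within its error. At day 7, 34.7% of the 75 members lay more than 2 SE from the list median, which argues against a common loss of green tissue as the whole cause there. The treatment stays a possible explanation that these tests did not separate from tissue share at day 14.

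At day 7, 104 isoflavonoid and pathogenesis-related genes rose. With the photosynthesis list mean as a covariate, 94.2% of them (98) were still called as rising, and their median rise went from 1.97 to 1.84. That list differed little between treatments at day 7 (median -0.17), so the covariate could remove little of these rises. It was also measured after treatment. The fit therefore does not decide whether the share of green tissue changed. A bound set beforehand on the log2 change of 61 conserved genes (90th percentile 0.261, against a median of 1.97 for the rising genes) was wrong for rising genes that started lower than these, whose log2 change a small oomycete share would raise more, and so does not decide. In normalised counts the conserved genes changed by -206 ± 138 (SE) per gene. The 70 rising genes that started at or above the 10th percentile of conserved-gene control levels (453) gained a median of 6816. The 34 below it gained a median of 1169. This argues against oomycete reads as the source of both gains as sets. A response of the seedlings to P. oligandrum is a hypothesis found and tested on the same data.

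Other libraries lay far from the rest of their group, on the log2 scale. The lowest was control day 3 replicate 2 for the shikimate O-hydroxycinnamoyltransferase MtrunA17_Chr3g0132831 (6.05), treated day 3 replicate 3 for the NLR gene MtrunA17_Chr8g0353351 (11.3), treated day 7 replicate 1 for the WRKY gene MtrunA17_Chr7g0228941 (6.39) and control day 3 replicate 3 for the flavonoid list mean (8.90). The highest was control day 5 replicate 2 for the peroxidase MtrunA17_Chr4g0013171 (9.48), control day 14 replicate 5 for caffeoyl-CoA O-methyltransferase MtrunA17_Chr4g0053021 (11.5), and treated day 14 replicate 5 for the WRKY genes MtrunA17_Chr1g0147881 (13.3) and MtrunA17_Chr8g0348311 (10.7). The sum of normalised counts of control day 3 replicate 1 was the lowest of its group, at 50.7 M.

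The effect of treatment differed between days in 7218 genes by the limma F test. The 10 named genes with the smallest adjusted interaction p were the germins MtrunA17_Chr2g0285871 (1.99e-09) and MtrunA17_Chr6g0449731 (1.03e-08), the kinase and WD40-like genes MtrunA17_Chr2g0317491 (1.99e-09) and MtrunA17_Chr8g0347471 (6.55e-09), the TauE gene MtrunA17_Chr7g0265481 (3.56e-09), the zinc/iron permease MtrunA17_Chr2g0328931 (3.56e-09), the sigma factor MtrunA17_Chr3g0126401 (6.55e-09), the dioxygenase MtrunA17_Chr1g0184101 (6.55e-09), the Ninja family gene MtrunA17_Chr7g0219081 (7.47e-09) and the NAM gene MtrunA17_Chr5g0442771 (7.80e-09). Of the other 96 named genes, 76 had an interaction call.

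Other splits of the same libraries were used to ask how often chance gave as many calls. In fits of the 12 libraries of each comparison alone, 1 of 100 splits, the real one, gave as many genes at day 3 (4873, highest other 26), day 5 (6614, highest other 4480), day 7 (9921, highest other 1), day 14 (4033, highest other 1) and between control days 14 and 3 (13717, highest other 0). The day 5 split with 4480 genes exchanged replicate 2 of both groups, the next had 33, and a fit of the 10 day 5 libraries left without replicate 2 of both groups, chosen after that split was seen, called 7326. Relabelling within days gave as many genes in 1 of 100 for the average (11803, highest other 2578) and in 1 of 100 for the interaction (7218, highest other 1826). With 100 splits or relabellings for each, 1 in 100 was the smallest share possible. For each of the 7 results these counts made chance unlikely as the source of the number of calls, but did not exclude it. They say nothing about single genes.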

How the results depend on the processing

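The settings without control day 14 replicate 3, with a mean of at least 200, with the photosynthesis covariate, with limma on 10 libraries and with permutation of list means were chosen after the data were seen. No named gene reversed its direction and no called list test turned. Without the filters that removed 0 genes, of 2480 values of named genes under alternatives 2433 kept their direction and side of the threshold and 47 lost the call, while of 1296 list tests 1181 kept theirs, 39 gained a call and 76 lost one. The medians of 2 called lists changed sign with quantile normalisation, those of the 14 called between control days kept theirs under both scalings (looked at after the data were seen), and the balance of rising and falling calls changed sides under some settings. Requiring a log2 fold change of at least 1 left 297, 860, 1485 and 1020 genes at the 4 days, 685 on average and 3758 between control days, by construction. Fits of the libraries of a comparison alone gave 4033 genes at day 14, and 4873, 6614, 9921 and 13717 at days 3, 5, 7 and between control days, where the cause was not tested. Weights per library gave 9467 genes at day 5 and 10914 for the interaction, and the cause was not tested. With an estimated correlation camera called 0 of 108 list tests (7 at an unadjusted p below the threshold), against 35 with the preset one, 37 by fry and 39 by exact permutation.

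Leaving out each replicate number gave 2319 to 4221 genes at day 3, 4272 to 6486 at day 5, 7729 to 8878 at day 7, 5927 to 7243 at day 14, 10349 to 11413 on average, 14241 to 14617 between control days, 4367 to 6772 for the interaction and 31 to 37 list calls, with fewer libraries in each. The lowest day 3 counts were without replicate 1 (2319), 6 (2324) and 5 (2363), and that of the interaction without replicate 5. Without control day 14 replicate 3 the counts were 6089 at day 14 (3131 up and 2958 down, main 3636 and 3756), 12038 on average, 14842 between control days and 7232 for the interaction, with 35 list calls of which 34 were shared. Quantile normalisation gave 2490 up and 3923 down at day 5 (main 3090 and 3122), 3941 up and 6394 down at day 7 (main 5043 and 4545) and 4831 up and 6897 down on average (main 5951 and 5852). On recovered day 3 reads edgeR called 2935 genes (987 up and 1948 down), DESeq2 3961 (9 with no adjusted p) and limma on the same 10 libraries 2904. With the photosynthesis covariate 4651, 5782, 11322 and 4994 genes were called at the 4 days and 10944 on average. Of the 4994 at day 14, 2165 were among the 7392 in the same direction and 105 in the opposite one. Of the 18384 genes with a mean of at least 200, 3454, 5653, 8531 and 6607 were called at the 4 days.

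The replicate numbers were not used as pairs, since no label says that they mark a shared batch. Of 24 correlations between treated and control libraries of the same number, 7 were above 0.1 (range -0.365 to 0.356, median 0.0229), and 4 libraries correlated best with their own number. Over all groups the mean correlation was 0.0397 for the same number and -0.00808 for other numbers, so a weak shared effect is not excluded. With the replicate number as a block, 3838, 6405, 9784 and 7565 genes were called at the 4 days, 11940 on average, 15237 between control days, 7581 for the interaction and 35 list tests. The filters planned (no filter and 5 times the minimum) removed 0 genes and say nothing about stability. Count tests were not run for days 5, 7 and 14, the average, the interaction and the control comparison, because the stricter rule on low values did not recover reads in 35 libraries. For low genes, a control mean near 0 leaves a fold change that depends on the pseudocount, and depth as a limit on them was not tested.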

Other observations

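The gene families, the metal transport genes and the genes listed by symbol were looked at after their values were seen. A set of 23 genes had the words chalcone synthase in their description, and some of them were described as 6'-deoxychalcone synthases. Of these 23, 13, 19, 19 and 17 rose and 1, 1, 1 and 1 fell at days 3, 5, 7 and 14. They had 14 interaction calls, and after quantile normalisation 12, 19, 19 and 17 rose. MtrunA17_Chr7g0252331 fell by 1.36 ± 0.20 at day 3, fell by 1.26 ± 0.20 at day 5 and fell by 1.34 ± 0.20 at day 7, and differed by -0.25 ± 0.20 (adjusted p = 0.365) at day 14. The gene that fell at day 14, by 0.97 ± 0.24 (adjusted p = 0.00165), was MtrunA17_Chr1g0173621, described as a 6'-deoxychalcone synthase. Of 42 genes described as lipid transfer proteins, 2, 1, 4 and 3 rose and 7, 9, 8 and 7 fell at the 4 days, and after quantile normalisation 5 rose and 15 fell at day 7. The 4 that fell most at day 3 had no fall called at days 7 or 14. MtrunA17_Chr1g0205171 was then called higher, by 0.95 ± 0.36 (adjusted p = 0.0279) and 1.01 ± 0.36 (adjusted p = 0.0253). In controls MtrunA17_Chr1g0205201 itself went from 1559 ± 443 normalised counts at day 3 to 143 ± 52.2 at day 7. Of 28 Bet v I/major latex proteins, 4, 11, 11 and 10 rose and 1, 10, 8 and 9 fell at the 4 days, with medians of 0.09, -0.05, -0.03 and 0.14, and after quantile normalisation 11 rose and 12 fell at day 5. Of 17 germins, 5, 6, 6 and 8 rose and 0, 1, 4 and 1 fell, at medians of 0.14, 0.02, -0.13 and 0.44.

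Some metal transport genes were picked by hand from those that rose in controls between days 3 and 14. In treated against control seedlings at day 14, the zinc/iron permease MtrunA17_Chr4g0043491 rose by 1.67 ± 0.32 (adjusted p = 5.77e-05) and kept its call in 6 of 6 leave-outs of a replicate number. The ferric-chelate reductases MtrunA17_Chr8g0348521 and MtrunA17_Chr8g0348531 rose by 2.24 ± 0.89 (adjusted p = 0.0483) and 2.70 ± 0.84 (adjusted p = 0.0113), with calls kept in 2 and 5 of 6 leave-outs. An NRAMP gene (MtrunA17_Chr3g0124971) rose by 1.59 ± 0.59 (adjusted p = 0.0340), with its call kept in 3 of 6. Without control replicate 3 the adjusted p for MtrunA17_Chr8g0348521 was 0.0891 and for MtrunA17_Chr3g0124971 0.0831. The nicotianamine synthase MtrunA17_Chr2g0312871, looked at with them, differed by 1.41 ± 0.67 (adjusted p = 0.101), which is not a call. Nor was there a call for the cation efflux protein MtrunA17_Chr3g0119281, which that choice left out and which differed by 1.37 ± 0.72 (adjusted p = 0.140). The SE of each change came from the spread within all 8 groups, not from day 14 alone. At day 14, 6 of 6 treated pools stood above the highest control for MtrunA17_Chr4g0043491 and both ferric-chelate reductases. For the NRAMP gene and the nicotianamine synthase 5 of 6 did. Of 27 iron and zinc homeostasis genes, 6 rose and 5 fell at day 14. Camera with the preset correlation made no call for that list, while exact permutation called a rise (adjusted p = 0.0111).

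Genes listed by symbol only had no description. MtLYR4, a member of the LysM receptor family, differed by 0.46 ± 0.11 (adjusted p = 8.01e-04) at day 5, 0.62 ± 0.11 (adjusted p = 6.93e-06) at day 7 and 0.45 ± 0.11 (adjusted p = 9.36e-04) at day 14. MtERN1 differed by -1.19 ± 0.31 (adjusted p = 0.00206) at day 7. MtENOD40 differed by 0.34 ± 0.11 (adjusted p = 0.0255) at day 3, and MtATB2 by 0.43 ± 0.10 (adjusted p = 0.00163) at day 3, -0.30 ± 0.10 (adjusted p = 0.0105) at day 7 and -0.46 ± 0.10 (adjusted p = 2.88e-04) at day 14. MtbHLH658 differed by -0.26 ± 0.10 (adjusted p = 0.0382) at day 7 and 0.30 ± 0.10 (adjusted p = 0.0202) at day 14. The other 4 of these 9 genes had no call on any day.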
